A study of Glycine max with 97 samples.

How the data were processed

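The series holds 97 samples of soybean (Glycine max) leaves at 3 weeks of age. Methylomes of 4 lines and 12 RNA-seq libraries, 3 per line, were analysed; 81 further methylome samples labelled as other recombinant inbred lines were not analysed here, nor were genomic reads of the parents. Groups were taken from the sample titles and genotype labels. The column descriptions call all 3 RNA columns of RIL-11272 the first replicate; they hold different values and were taken as replicates 1 to 3 by their column names. Every column of sample values was used.

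Per the labels' protocols, leaf DNA was made into MethylC-Seq libraries. The methylome files give counts deposited by the authors for each listed cytosine, the methylated reads and all reads, with chromosome, position, strand and context. Every listed cytosine had at least 1 methylated read, so the lists hold cytosines called methylated, and the calling threshold is not given in the sources used here. No listed cytosine had over 101 reads in any of the 4 methylomes; whether depth was capped or duplicate reads removed is not given there either, and the mean depths and dosages hold for the reads as listed. Bowtie 0.12.7, TopHat 1.3.3 and Cufflinks 1.1.0 are named in the submitters' processing notes. The genome build and annotation are not given in the sources used here, and coordinates are those of the files, counted from 1.

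The expression table holds RPKM values per transcript and library, as deposited by the authors. Its library sums lay between 13,791,500,000 and 24,479,700,000, far above the usual scale of RPKM, and the reason is not given in the sources used here. All values were therefore divided by a single constant, 15251.1, which brings the median library sum to 1000000. This constant was chosen after the scale was seen and is the same for every gene and library, so that the pseudocount and filter fixed beforehand keep their meaning; the values are called rescaled RPKM. The 66,879 transcripts were summed to 64,679 genes, 64,253 of them on the 20 chromosomes. Low values were compared between libraries for steps of 1 read. At most 19.4% of low values lay at a common step, so whole reads could not be recovered and the RNA depth is unknown. None of the 64,679 gene identifiers matched the soybean gene table at hand, made for assembly Glycine_max_v4.0, so genes are given by identifier. The names of the genes fixed beforehand (Rhg1, Rhg4, E2, E3, E4, FT2a, FT5a, Dt1 and the vegetative storage proteins) are general knowledge and not from the files. Gene lists by product description could not be formed without such names. The E1 gene was not analysed here.

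Expression was tested with limma 3.58.1 in R 4.3.3 on log2(rescaled RPKM + 1), with all 12 libraries in 1 fit, a mean per line, 8 residual degrees of freedom, a trended prior and no robust weights. Genes with a value of at least 1 in at least 3 libraries were kept, 36,565 in all. A call is a Benjamini-Hochberg adjusted p under 0.05. On simulated libraries for LDX against LD over the 36,565 genes, the test recovered 10% of genes changed by 1 on the log2 scale, 64% at 2, 96% at 4 and 100% at 6, with 8 false calls. The rule for naming genes was fixed before the data were examined: the calls with the largest rise and fall whose replicates do not overlap, and a list of known loci. As the files do not pair identifiers with names, at most 2 identifiers each way are printed per comparison, besides the named loci.

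Inheritance of expression was scored at genes called between the parents with at least a 2-fold difference. The position of an inbred line between the parental means on the log2 scale gave the LD state at 0.25 or less and the LDX state at 0.75 or more. The share of adjacent genes with the same state was compared with 10000 permutations of the states within chromosomes, genes being ordered by identifier, and with 2000 permutations for other settings. Libraries were simulated in 20 draws with the fitted spread, with the parental genes called anew in each draw. A version that keeps the 241 genes of the real libraries was added after the first was seen. The first calls more parental genes than the real libraries gave, and the second takes the parental differences as true. The first also gave a larger intermediate share than RIL-11272 showed, so it overstates the background there. How far the second understates it is open.

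Methylation levels are methylated reads over all reads at listed cytosines, with Wilson 95% intervals. The parents were compared at cytosines listed in both with at least 10 reads in each, and in 200 bp windows with at least 3 such cytosines of at least 3 reads and 20 reads in each library, by 2-sided Fisher's exact tests with Benjamini-Hochberg adjustment per context. A call needs an adjusted p under 0.01 and a difference of at least 0.4, or 0.2 for CHH. Windows with at least 5 listed CG cytosines in 1 parent and 0 in the other were counted with no test per window. In the inbred lines the number of listed cytosines relative to the parent gave the state, by the same limits of 0.25 and 0.75. Neighbouring windows were compared with 1000 permutations within chromosomes. Bins of 1 Mb with at least 10 decided windows were called mostly LD at an LDX share of at most 20%, mostly LDX at 80% or more, and mixed between. The methylated-read dosage of a parental type in a bin is the methylated reads of the inbred line at windows of that type over those of the parent, scaled by the reads at windows listed in both parents. The tests were tried on simulated data first. Correlations over chromosomes used 100000 permutations. Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, numba 0.67.0 and matplotlib 3.10.9 was used.

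Alternatives covered the pseudocount, the filter, quantile normalization, the prior, a replicate block, the libraries in the fit, each library left out, and the minimum fold, as well as read minimums, window sizes, thresholds, context and state limits. Settings added after the data were examined were the fits without 3 libraries that stand apart or with them as a covariate, the test of transcripts as deposited, the coverage minimum for the inheritance of windows called by level, and the comparison of assays by chromosome.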

Results

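Leaves of 3-week-old soybean plants were profiled for DNA methylation and for RNA in parental lines LD and LDX and in the recombinant inbred lines RIL-11268 and RIL-11272. A recombinant inbred line is made by repeated selfing after a cross, so its chromosomes are mosaics of segments from either parent. Each line had 1 MethylC-Seq library, which reports methylation at single cytosines after bisulfite conversion, and 3 RNA-seq libraries. The methylome of LD listed 44,015,122 cytosines at a mean of 14.4 reads each, and that of LDX listed 45,755,906 at 12.9 reads. The shallower methylomes of RIL-11268 and RIL-11272 listed 34,623,553 cytosines at 8.94 reads and 35,731,956 at 10.9 reads. Each methylome listed only cytosines called methylated, so a cytosine missing from a list was either unmethylated or not covered. With 1 methylome per line there was no replicate error for methylation, and those comparisons are between libraries. The labels do not say whether the 3 RNA libraries of a line came from separate plants, so the p-values for expression measure only the spread between these samples, which may be technical. The comparisons ask how the parents differ in methylation and expression and which parent each inbred line resembles at each differing locus.

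Methylation at listed CG cytosines was near complete in all 4 lines, while levels were lower at CHG and lowest at CHH cytosines (H is A, C or T). The level, the share of reads that were methylated, was 95.9% at CG in LD, 95.8% in LDX, 96.0% in RIL-11268 and 96.3% in RIL-11272. At CHG it was 75.9% in LD, 75.1% in LDX, 77.1% in RIL-11268 and 76.6% in RIL-11272. CHH cytosines stood at 28.1% in LD, 30.0% in LDX, 34.4% in RIL-11268 and 33.4% in RIL-11272. The Wilson 95% intervals of these shares, which cover counting error only, were at most 0.0214 percentage points wide. Cytosines covered by at least 10 reads gave CHH levels of 25.2%, 26.7%, 28.8% and 28.3% in the same order, so the CHH levels of the inbred lines moved with the depth of the cytosines included. In RIL-11272, CHG cytosines under 3 reads held only methylated reads. Without them, all reads fell from 134,848,162 to 133,321,300 and methylated reads from 103,226,468 to 101,699,606. In RIL-11268 such cytosines also held unmethylated reads. The calling rule thus appears to differ between lines, which limits comparison of their levels and listed numbers. LD and LDX shared most of their listed CG cytosines, 14,136,290, or 91.5% of those of LD and 91.1% of those of LDX. For CHH the shared part was 60.0% of the cytosines of LD and 53.3% of those of LDX.

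Where the same cytosine was listed in both parents, its level seldom differed. Among 6,094,981 CG cytosines with at least 10 reads in each parent, 12,345 (0.203%) differed by at least 0.4 in level at an adjusted p under 0.01. LDX was higher at 7,032 of them and LD at 5,313. CHG cytosines differed at 5,497 of 6,063,474 sites, LD being higher at 3,126, and CHH cytosines at 602 of 4,867,598 sites with a difference of at least 0.2. In 200 bp windows 2,072 of 1,253,398 windows differed in CG, 1,346 of them higher in LDX, against 2,580 of 1,377,283 in CHG, 1,556 of them higher in LD, and 665 of 1,127,157 in CHH. These counts come from 2-sided Fisher's exact tests on the methylated and unmethylated reads of the LD and LDX libraries, with Benjamini-Hochberg adjustment per context. On simulated reads for chromosome 13 the window test recovered 93.5% of CG windows and 57.5% of CHG windows with a difference of 0.5, and 9% of CHH windows with a difference of 0.3. A difference of at least 0.6 (0.3 for CHH) left 504 CG, 458 CHG and 284 CHH windows, and doubling the coverage minimum left 1,181 CG windows.

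A larger contrast lay in regions that only 1 parent listed as methylated. In 40,725 windows of 200 bp, together 8.145 Mb, at least 5 CG cytosines were listed in 1 parent and none in the other. They were 3.41% of the windows with that many listed in either parent. LD alone listed 23,236 of them and LDX alone 17,489. The parent without listed CG cytosines seldom listed any cytosine of another context there: LD did so in 7.80% of the windows listed in LDX alone, and LDX in 7.44% of those listed in LD alone. The windows were concentrated on chromosomes 18, 15, 19, 3 and 4, which held 23,983 of them (58.9%), and the densest 10% of 1 Mb bins held 53.8%. On chromosome 19, LDX alone listed 4,273 of 4,482 windows (95.3%), whereas on chromosome 4 LD alone listed 3,181 of 3,617 (87.9%) and on chromosome 18 5,429 of 6,955 (78.1%). The densest bin was on chromosome 4 at 32,000,001 to 33,000,000, with 791 windows, against a median of 15 per bin. Coordinates are those of the deposited files, whose genome build is not given in the sources used here. Read depth moved with direction over the 405 bins with at least 20 windows. The median ratio of LD to LDX reads, at CG cytosines listed in both, was 1.08 in these bins. It was 1.18 in the 124 with at least 4 times as many windows of LD alone as of LDX alone. In the 80 with the reverse excess it was 0.982. The number of windows depended on the definition, with 76,410 at 3 or more listed cytosines, 22,826 at 8 or more and 24,156 in windows of 500 bp.

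Most of these windows took the state of 1 parent in each inbred line, and LD states prevailed. In RIL-11272, 24,090 windows were in the LD state (at most 0.25 of the way from LD to LDX in listed cytosines), 11,603 in the LDX state (at least 0.75) and 5,032 between. In RIL-11268 the numbers were 18,411, 13,918 and 8,396, so 20.6% of windows were intermediate there against 12.4% in RIL-11272. Of the windows with a parental state, 43.1% were LDX in RIL-11268 (exact binomial 95% interval 42.5 to 43.6) and 32.5% in RIL-11272 (32.0 to 33.0). These intervals treat windows as independent, although neighbours are linked. Among 28,996 windows with a parental state in both inbred lines, 57.0% had the same state. As background, RIL-11268 listed none of the CG cytosines in 1.95% and RIL-11272 in 1.57% of the 1,046,752 windows listed in both parents, and 615 and 808 windows had at least 5 in the inbred line and none in either parent. Of the windows listed in both parents, where no difference was sought, 14.8% in RIL-11268 and 11.1% in RIL-11272 likewise had between 0.25 and 0.75 of the parental number, so much of the intermediate share is background. At the CG windows called by level, of which 1,149 of 2,072 could be measured in RIL-11268 and 1,190 in RIL-11272, the LDX share was 55.1% and 56.6%. At the doubled coverage minimum, tried after the data were seen, it was 50% (exact binomial 95% interval 45.2 to 54.8) and 52.2% (47.6 to 56.7). Both intervals hold an even share. At the CHG windows called by level the share was 34.6% and 23.0%, with LD states the more common. Only windows where the inbred line itself listed cytosines could be measured, so a low parental type can be missed. This can favour the parent with the higher level. That was LDX in 1,346 of 2,072 CG windows and LD in 1,556 of 2,580 CHG windows. The shares by level thus do not show which parent prevailed.

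Parental states ran in blocks along the chromosomes, long on some, such as 4 and 19, and shorter or mixed on others. Chromosome 19 was 95.3% LDX in RIL-11272 and 4.47% LDX in RIL-11268, among windows with a parental state, while chromosome 18 was 18.5% LDX in RIL-11272 and 84.8% in RIL-11268. Chromosome 4 was LD in both, at 6.503% and 7.04% LDX. Chromosome 15 was LD in RIL-11272 (11.6% LDX), whereas in RIL-11268 34.6% of its windows were intermediate, against 26.5% so listed among its windows listed in both parents (23.8% in RIL-11272). Adjacent windows shared a state in 87.1% of pairs in RIL-11272, against a mean of 72.1% when states were permuted within chromosomes, and in 82.0% against 67.7% in RIL-11268. Both permutation p were 0.001, the smallest that 1000 permutations can give, and the shares were still 83.6% and 78.0% in pairs at least 10 kb apart. Of the 1 Mb bins with at least 10 such windows, 259 of 580 were mostly LD and 156 mostly LDX in RIL-11272, with 165 mixed. In RIL-11268 217 of 584 were mostly LD, 146 mostly LDX and 221 mixed.

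**Figure D1:**
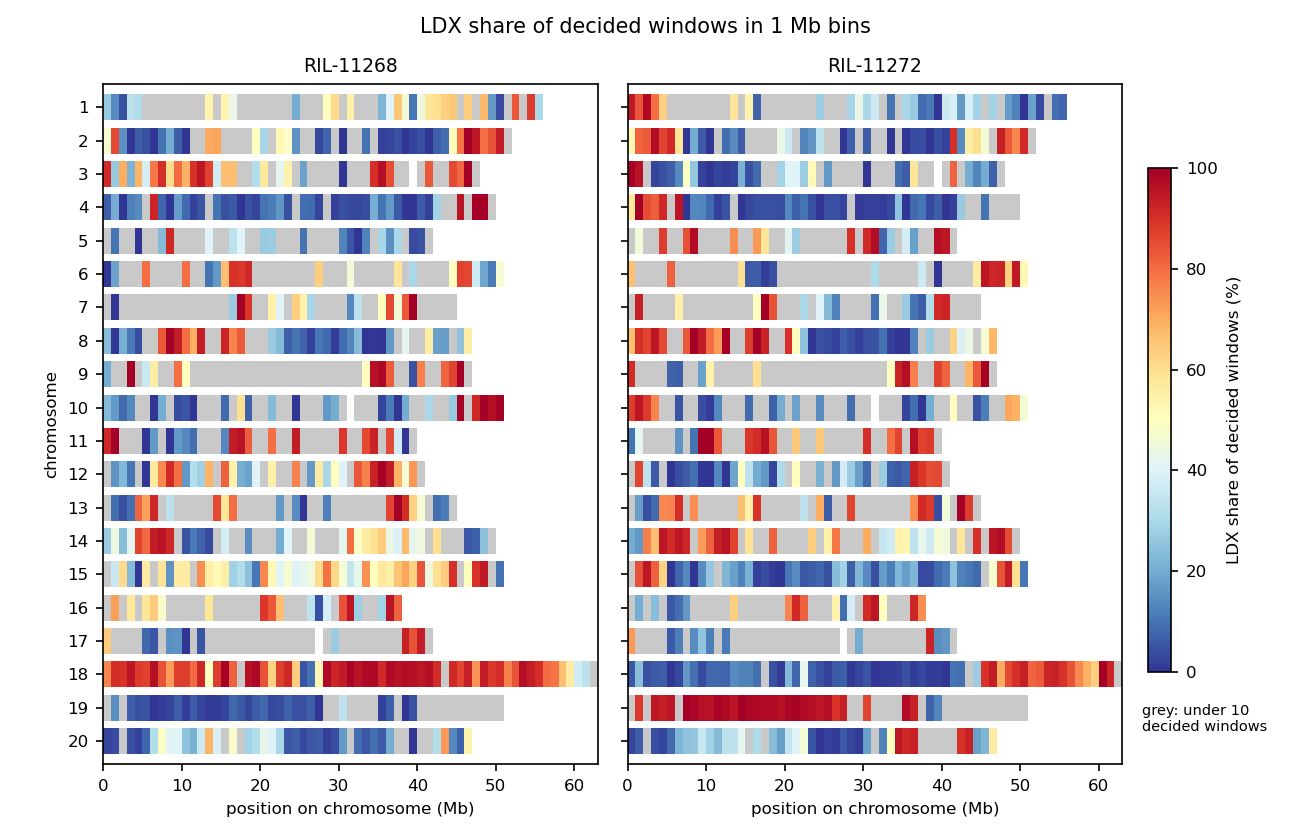
Each bar is 1 chromosome in 1 Mb bins, with position in Mb on the horizontal axis and colour for the LDX share of the windows with a parental state, from blue (LD) to red (LDX); grey bins held under 10 such windows. Chromosome 19 is blue in RIL-11268 (4.47% LDX) and red in RIL-11272 (95.3%), and chromosome 15 of RIL-11268 holds many bins of mid colour.

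The longest runs of adjacent windows showed the same kinds of inheritance at single regions. At chromosome 4, 33,637,601 to 33,643,800, LD listed 519 CG cytosines and LDX none, and RIL-11268 listed 478 and RIL-11272 515. At chromosome 18, 52,013,801 to 52,019,000, LD listed 499 and LDX none, and the inbred lines listed 3 and 8, the LDX state. The run at chromosome 3, 6,243,401 to 6,248,600, with 343 in LD and none in LDX, had 209 in RIL-11268 (60.9% of LD, intermediate) and 294 in RIL-11272. LDX alone listed 475 CG cytosines at chromosome 3, 11,583,401 to 11,589,600, where RIL-11268 listed 330 (69.5% of LDX, intermediate) and RIL-11272 listed 1. A run of LDX alone at chromosome 3, 12,476,601 to 12,482,200, had 413 in LDX, 348 in RIL-11268 and 24 in RIL-11272. At chromosome 1, 3,744,001 to 3,748,800, LDX listed 399 and LD none, and both inbred lines were intermediate at 236 and 273. RIL-11268 was the library with the fewest reads per cytosine, which lowers the number of cytosines it can list. At the chromosome 4 run it held 2,805 methylated reads against 5,348 in LD. Its intermediate runs held fewer relative to the parent. These were 564 against 4,771 and 881 against 3,590 on chromosome 3, and 793 against 3,521 on chromosome 1. The LDX-state run on chromosome 3 lay between, at 1,255 against 3,378. Low depth of the whole library alone would not give so uneven a share.

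Between the parents, 243 genes differed in expression, 97 higher and 146 lower in LDX, and the largest changes were close to presence against absence. Glyma02g36640 stood at 239 ± 27.9 (SD, n = 3) in LDX and at 0.176 ± 0.305 in LD, a log2 difference of 7.70 (SE 0.29, adjusted p 5.68e-07). Glyma19g11560 was listed at 0 in the 3 LD libraries and at 43.2 ± 12.1 in LDX (adjusted p 3.46e-05). Glyma02g03230 went the other way, from 1103 ± 372 in LD to 0.764 ± 0.124 in LDX, a log2 difference of -9.24 (SE 0.31, adjusted p 2.81e-07), and Glyma04g35130 from 739 ± 357 to 1.11 ± 0.368, a log2 difference of -8.36 (SE 0.55, adjusted p 1.74e-05). Values are rescaled RPKM, the p-values are from limma with Benjamini-Hochberg adjustment over 36,565 genes, and fold changes are on the log2(value + 1) scale, which understates the change of low genes. At least 2-fold was reached by 241 of the 243 genes, and in all 243 the 3 LD libraries did not overlap the 3 LDX libraries. The genes were called on these same libraries, so this separation is no separate support. LD replicate 2, LDX replicate 3 and RIL-11272 replicate 1 stood apart from the other 9 libraries on a principal component holding 56.9% of the variance; with these 3 as a covariate the count was 603, and with the 6 parental libraries alone 119. Without LD replicate 1, LD replicate 2 or LDX replicate 2 it was 131, 156 and 151.

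Of the genes fixed by identifier beforehand, the Rhg1 region, a locus for resistance to soybean cyst nematode, held the only call between the parents. Glyma18g02580, an amino acid transporter of that region, was at 139 ± 59.6 in LD and 29.2 ± 14.2 in LDX, a log2 difference of -2.23 (SE 0.41, limma with Benjamini-Hochberg adjusted p 0.0361). RIL-11268, at 30.97 ± 4.59, was like LDX, and RIL-11272, at 59.6 ± 29.2, lay between the parents. Its neighbours Glyma18g02590 (187 ± 104 in LD, 79.9 ± 26.5 in LDX) and Glyma18g02610 (241 ± 123 and 63.7 ± 37.4) did not pass, with limma Benjamini-Hochberg adjusted p of 0.839 and 0.636. The vegetative storage protein gene Glyma07g01730 was at 2813 ± 1494 in LD and 590.8 ± 296 in LDX and did not pass (limma, Benjamini-Hochberg adjusted p 0.586), nor did the flowering gene FT5a (Glyma16g04830), at 12.7 ± 7.21 and 24.98 ± 1.33 (limma, Benjamini-Hochberg adjusted p 0.456). The maturity genes E2, E3 and E4, FT2a, the storage protein gene Glyma08g21410 and the Rhg4 region gene Glyma08g11490 did not pass either, each with a limma Benjamini-Hochberg adjusted p of 1. The stem growth gene Dt1 (Glyma19g37890) was listed at 0 in all 12 libraries. The call of Glyma18g02580 was lost without LD replicate 1, 2 or 3 (limma, Benjamini-Hochberg adjusted p 0.149, 0.177 and 0.0514) and without LDX replicate 1 or 2 (0.159 and 0.194).

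**Figure D2:**
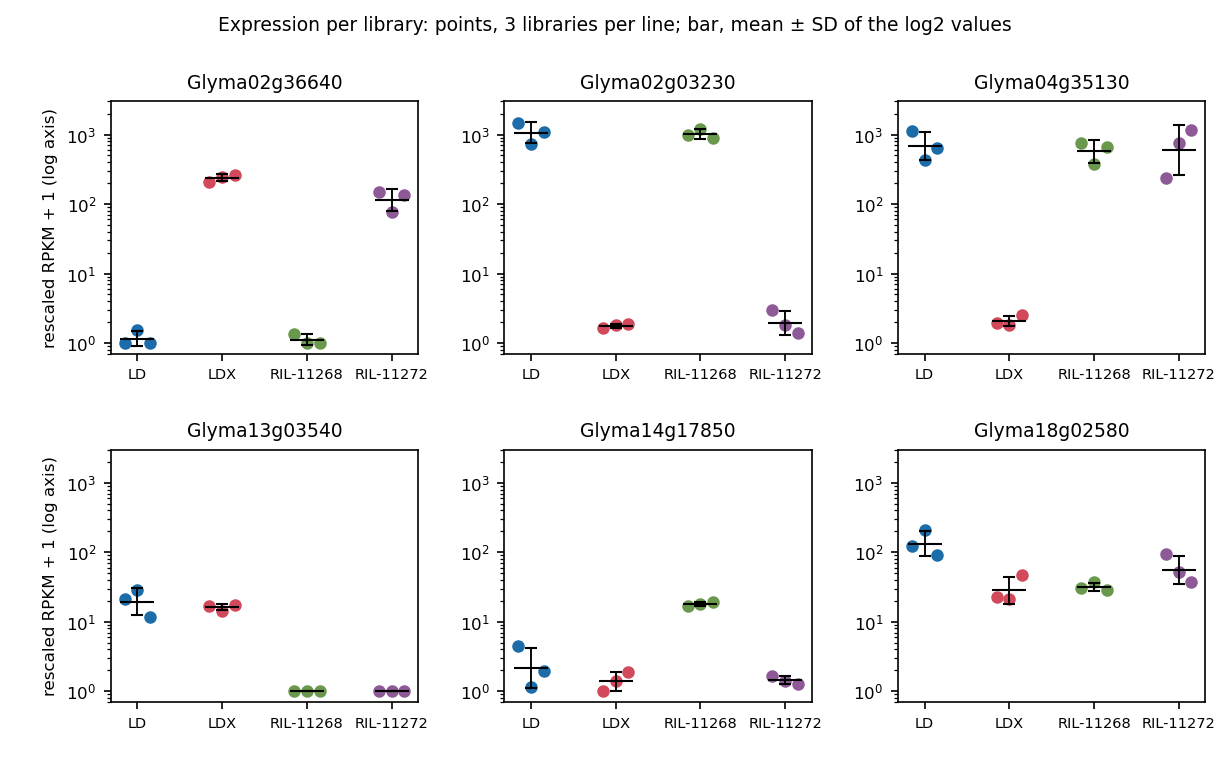
Rescaled RPKM plus 1 on a log axis for 6 genes, with 1 point per library, 3 libraries per line, and bars for the mean and SD of the log2 values. Glyma02g36640 is near the floor in LD and RIL-11268 and at 239 and 119 in LDX and RIL-11272, while Glyma13g03540 is at the floor in both inbred lines and in neither parent.

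RIL-11268 differed from LD at 66 genes, 32 higher and 34 lower, and from LDX at 114, 75 higher and 39 lower. Against LD, Glyma12g09750 was higher (17.98 ± 2.20 against 0.191 ± 0.169, limma Benjamini-Hochberg adjusted p 1.34e-05) and Glyma15g27470 stood at 15.2 ± 1.79 where LD was listed at 0. Lower were Glyma18g35940 (0.0282 ± 0.0488 against 30.8 ± 10.6, log2 difference -4.90, SE 0.28, limma Benjamini-Hochberg adjusted p 2.17e-05) and Glyma02g46310 (0.758 ± 0.842 against 50.4 ± 37.0). All 4 were in the LDX state. Against LDX, RIL-11268 had the LD state of Glyma02g03230 (1024 ± 162) and Glyma04g35130 (595.1 ± 197), and the low LD levels of Glyma02g36640 (0.122 ± 0.211) and Glyma19g11560 (0.552 ± 0.956). The count against LD fell to 26, 37 and 34 without LD replicate 1, 2 or 3 and rose to 101 with the 3 libraries that stand apart as a covariate. Its near-even split became mostly higher without those LD replicates (18 against 8, 23 against 14 and 21 against 13), in the 6 libraries alone (35 against 16) and without the 3 libraries that stand apart (36 against 22). The count against LDX was 56 and 65 without LDX replicate 2 or 3, 75 and 71 without RIL-11268 replicate 1 or 3, and 217 with that covariate.

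RIL-11272 differed from LD at 90 genes, 31 higher and 59 lower, and from LDX at 94, 54 higher and 40 lower. It was in the LDX state at Glyma02g36640 (119 ± 38.4, below the 239 ± 27.9 of LDX, log2 difference from LD 6.64, SE 0.29, limma Benjamini-Hochberg adjusted p 2.78e-06) and at Glyma19g11560 (50.9 ± 16.3), and low like LDX at Glyma02g03230 (1.04 ± 0.807). Glyma02g03220, at 41.9 ± 18.3 in LD, was listed at 0 in RIL-11272 and in LDX. Against LDX it was in the LD state at Glyma04g35130 (721.9 ± 466, log2 difference 8.16, SE 0.55, limma Benjamini-Hochberg adjusted p 3.46e-05) and at Glyma20g20350 (135 ± 91.5), and was low like LD at Glyma03g12150, listed at 0, and Glyma16g07530 (0.143 ± 0.248). Over all genes tested the median log2 difference of RIL-11272 from LD was -0.12, and -0.029 after quantile normalization. Leaving out any 1 of LD replicates 1 to 3 gave 31, 51 and 45 genes against LD, and leaving out RIL-11272 replicates 1 to 3 gave 58, 50 and 55; the 6 libraries of these lines alone gave 26, and the covariate 243. The excess of lower genes was absent in the 6 libraries alone (13 and 13), with the covariate (121 higher and 122 lower) and without the 3 libraries that stand apart (32 and 32). Against LDX the count was 62, 51 and 62 without LDX replicates 1 to 3, 59 without RIL-11272 replicate 2, 42 from the 6 libraries alone and 192 with the covariate. Its excess of higher genes was absent in the 6 libraries alone (21 and 21), without RIL-11272 replicate 2 (29 and 30), with no filter (47 and 47) and with a pseudocount of 5 (33 and 35).

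The inbred lines differed from each other at 70 genes, 23 higher and 47 lower in RIL-11272. The leading genes were again those on which the parents differed: Glyma02g36640 was higher in RIL-11272 by a log2 difference of 6.70 (SE 0.29, limma Benjamini-Hochberg adjusted p 2.55e-06) and Glyma02g03230 lower, with a log2 difference of -9.03 (SE 0.31, limma Benjamini-Hochberg adjusted p 3.57e-07). Glyma19g11560 was also higher (50.9 ± 16.3 against 0.552 ± 0.956), and Glyma02g03220, at 24.6 ± 2.41 in RIL-11268, was listed at 0 in RIL-11272. The count was 41 from the 6 libraries of these lines alone, and with the 3 libraries that stand apart as a covariate the directions were nearer even, 48 higher and 56 lower.

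At most of the 241 genes that differed at least 2-fold between the parents, each inbred line was like 1 parent. RIL-11268 was in the LD state at 117, the LDX state at 64 and between at 60, so 35.4% of its decided genes were LDX (exact binomial 95% interval 28.4 to 42.8). RIL-11272 was in the LD state at 109, the LDX state at 98 and between at 34, with 47.3% LDX (40.4 to 54.4). A 2-sided exact binomial test of equal shares, which treats linked genes as independent, gave p = 0.0001 for RIL-11268 and 0.487 for RIL-11272. Both outcomes hung on single libraries: without LDX replicate 2 the share in RIL-11268 was 42.3% (exact p 0.104), and without LD replicate 1 that in RIL-11272 was 39.8% (exact p 0.03005). Intermediate genes made up 24.9% of the genes in RIL-11268 and 14.1% in RIL-11272. Libraries simulated at the nearer parent gave 2.76% and 3.01% when the 241 genes were kept, and 24.5% in RIL-11268, with a like share in RIL-11272, when the parental genes were called anew in each draw, which took in a mean of 672.8 genes. Neighbouring genes shared a state in 86.0% of 186 pairs in RIL-11272, against 64.3% when permuted within chromosomes (permutation p 0.0001, the smallest that 10000 permutations can give), and in 82.1% of 162 pairs in RIL-11268 against 77.3% (permutation p 0.0067). In RIL-11268 the difference was lost at genes that differed at least 4-fold (permutation p 0.063) and with states split at the midpoint (permutation p 0.12).

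A few genes lay outside both parents. In RIL-11268 Glyma04g03770 was at 7.45 ± 1.90, against 0.265 ± 0.229 in LD and 0.570 ± 0.229 in LDX, and Glyma14g17850 at 17.0 ± 0.974, against 1.52 ± 1.71 and 0.439 ± 0.458. In RIL-11272 Glyma05g13910 was at 6.89 ± 2.38, against 0.0695 ± 0.1203 and 0.990 ± 0.635. Glyma13g03540 was listed at 0 in all 6 libraries of the inbred lines, while LD stood at 19.6 ± 8.30 and LDX at 15.2 ± 1.56. These genes passed limma with Benjamini-Hochberg adjustment against both parents in the same direction, 3 in RIL-11268 and 2 in RIL-11272, and were named after their values were seen. Simulated libraries at the nearer parent gave up to 5 such genes in RIL-11268 and 6 in RIL-11272 over 20 draws. Those draws called a mean of 672.8 parental genes, against 241 in the real libraries. Libraries simulated at LD, at LDX or at the midpoint gave at most 1 in RIL-11268 and 2 in RIL-11272. The 3 genes of RIL-11268 lay within the first range only, and the 2 of RIL-11272 within both. Whether the 3 exceed the background is thus open. The count in RIL-11272 was 1 without RIL-11272 replicate 2, LDX replicate 2 or LDX replicate 3, and 6 with the 3 libraries that stand apart as a covariate.

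By shares over whole chromosomes, methylation and expression placed the same parent on some chromosomes and not on others. Such shares follow where windows and genes are dense, so a gap does not show that the assays differ at a locus. In RIL-11272, chromosome 19 was 95.3% LDX by windows and 90.9% by genes, chromosome 5 75.0% and 100% on 4 genes, and chromosome 3 12.5% and 0%. Chromosome 8 was 24.1% LDX by windows but 81.8% by genes (9 of 11), chromosome 2 28.8% and 66.7% (12 of 18), and chromosome 20 17.6% and 50%. The windows of chromosome 8 were themselves split, with bins mostly LDX at 1,000,001 to 11,000,000 (165 windows) and 12,000,001 to 21,000,000 (167 windows). A dense block at 23,000,001 to 37,000,000 was mostly LD and held 1,474 of its 2,129 windows. On chromosome 20, bins at 23,000,001 to 33,000,000 were mostly LD (1,257 windows) and those at 34,000,001 to 44,000,000 mostly LDX (183 windows). Over 17 chromosomes with at least 3 decided genes the LDX shares gave a Pearson r of 0.797 (permutation p 0.00013, adjusted 0.000325) and a Spearman rho of 0.801 (permutation p 0.00016, adjusted 0.0004), with r at 0.743 without chromosomes 11 and 19. In RIL-11268, chromosome 18 was 84.8% LDX by windows and 93.9% by genes, but chromosome 3 was 71.5% by windows and 0% on 7 genes. Over 18 chromosomes its r was 0.468 (permutation p 0.051, adjusted 0.0638), rho 0.273 (permutation p 0.27, adjusted 0.338), and r was 0.203 without chromosomes 18 and 19. The intermediate shares of RIL-11268 moved together, with r 0.698 (permutation p 0.00092, adjusted 0.00153) and rho 0.597 (permutation p 0.01, adjusted 0.0167), although r was 0.462 without chromosomes 3 and 15. Those of RIL-11272 gave r 0.256 (permutation p 0.3, adjusted 0.3) and rho 0.192 (permutation p 0.44, adjusted 0.44). Chromosomes with more differing windows also had more genes differing between the parents, with r 0.808 (permutation p 5e-05, adjusted 0.00025), rho 0.879 (permutation p 1e-05, the smallest that 100000 permutations can give, adjusted 5e-05), and r 0.665 without chromosomes 15 and 18. Both are raw counts, not scaled by chromosome length or by genes tested, so the relation does not show a local link. These 5 relations, adjusted together by Benjamini-Hochberg, were chosen after the data were seen, in place of a comparison by gene position, for which no gene coordinates were at hand.

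**Figure D3:**
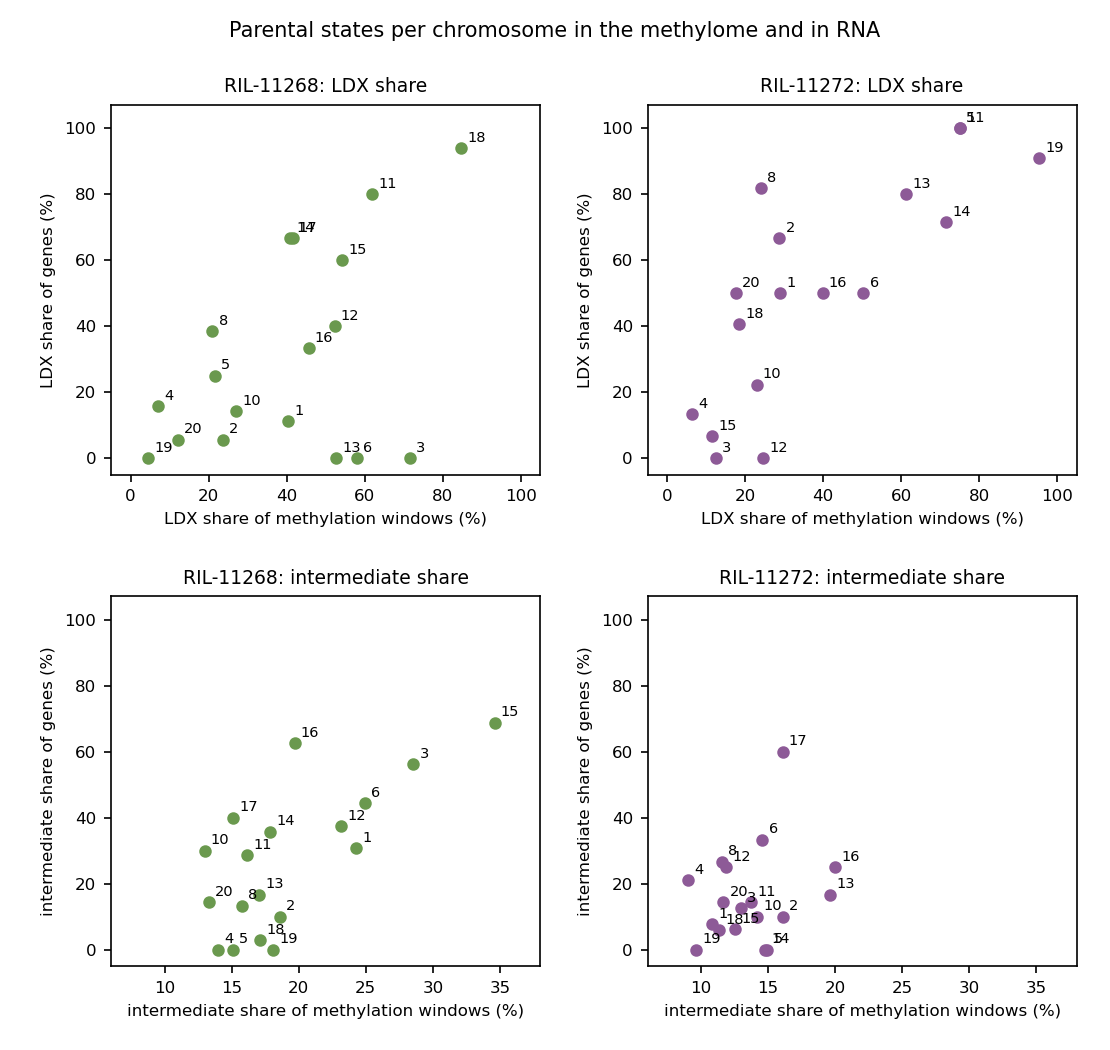
Each point is 1 numbered chromosome with at least 3 genes, with the share of methylation windows (%) on the horizontal axis and the share of genes (%) on the vertical axis, for LDX states (top) and intermediate states (bottom) in each inbred line. Among these, chromosome 15 of RIL-11268 has the largest intermediate shares, 34.6% of windows and 68.8% of genes.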

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

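The counts of other splits below were chosen after the results were seen. The 70 genes that differ between RIL-11272 and RIL-11268 are the genes whose change against LD differs between the lines, by a limma test of that difference with Benjamini-Hochberg adjustment. Glyma02g36640, Glyma19g11560, Glyma02g03230 and Glyma02g03220, which lead them, all differ between the parents. The next highest count among the 10 splits of those 6 libraries was 1 gene.

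For LDX against LD the 243 genes stood against 0 in every other split of the 6 libraries, as did 66 for RIL-11268 against LD, 114 for RIL-11268 against LDX and 90 for RIL-11272 against LD. For RIL-11272 against LDX the 94 genes stood against a highest other count of 1. Groups of 3 libraries give 10 splits, too few for a share under 0.05.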

How the results depend on the processing

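Fits without the 3 libraries that stand apart, with them as a covariate, or on single transcripts, the 5-gene minimum per chromosome, and the coverage minimum for inheritance by level were chosen after the data were seen. Of 296 settings tried on the 37 counts, shares and tests that answer a comparison, 204 left the result within its limits, 86 moved it, 3 ended a call, 1 gave a new call and 2 turned its direction. Single genes and correlations are not in that tally. Gene list tests and their alternatives were not run, since no gene names were at hand, and expression against the nearest 5 or 11 windows was not run, since no gene coordinates were at hand.

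Expression counts are given in the order LDX against LD, RIL-11268 against LD and LDX, RIL-11272 against LD and LDX, and RIL-11272 against RIL-11268. Leaving out 1 library of the lines compared gave 131 to 190, 26 to 47, 56 to 89, 31 to 58, 51 to 103 and 48 to 55 genes, with fewer samples in each fit. Leaving out a library of another line can raise the count. Without RIL-11272 replicate 1, 297 genes of at least 2-fold were called for LDX against LD, against 241. The 3 libraries as a covariate gave 603, 101, 217, 243, 192 and 104. The libraries of the compared lines alone gave 119, 51, 82, 26, 42 and 41, with fewer residual degrees of freedom. The replicate block gave 170, 47, 79, 49, 71 and 52 genes, and only RIL-11272 against LD moved by over 1.5 times. The replicate numbers do not pair the libraries: 5 of 18 same-number pairs had deviations correlated above 0.1, the range was -0.855 to 0.591, and 4 of 12 libraries correlated best with their own number. With the replicate block Glyma18g02580 had a limma Benjamini-Hochberg adjusted p of 0.135, over a range of 4.0e-05 to 0.194 in all settings. Its neighbour Glyma18g02590 passed with the covariate only (limma, Benjamini-Hochberg adjusted p 0.0179).

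With 1 library left out the LDX share of genes was 28.6% to 42.3% in RIL-11268, highest without LDX replicate 2 (exact binomial p 0.104), and 39.8% to 51.4% in RIL-11272, lowest without LD replicate 1 (0.03005). Adjacent genes in RIL-11268 shared a state in 80.4% of pairs at 4-fold genes (permutation p 0.063) and 73.2% with states split at the midpoint (0.12); the cause was not tested. Genes outside both parents numbered 1 in RIL-11268 with a pseudocount of 0.1. In RIL-11272 they numbered 1 to 3 with 1 library left out (1 without LDX replicate 2, LDX replicate 3 or RIL-11272 replicate 2), 1 without the 3 libraries that stand apart and 6 with the covariate.

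Methylation levels, given for CG, CHG and CHH, were at cytosines with at least 3 reads 95.9%, 75.7% and 27.9% in LD, 95.8%, 74.9% and 29.8% in LDX, 95.9%, 76.6% and 33.9% in RIL-11268 and 96.2%, 76.3% and 33.0% in RIL-11272. At 10 reads they were 95.8%, 74.8% and 25.2%, 95.7%, 73.8% and 26.7%, 95.5%, 74.5% and 28.8%, and 96.0%, 75.0% and 28.3%. Unweighted they were 96.4%, 79.7% and 37.5%, 96.4%, 78.8% and 38.2%, 96.9%, 82.3% and 45.2%, and 97.2%, 79.8% and 43.8%. The intervals used as limits cover counting error only and are narrow, so small moves count. The cause of the moves was not tested.

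Windows differing by level numbered 504 in CG, 458 in CHG and 284 in CHH at the larger difference, and 1,181 in CG at the doubled coverage minimum. Windows listed in 1 parent numbered 76,410 at 3 cytosines, 22,826 at 8 and 24,156 at 500 bp. Their LDX share in RIL-11268 was 44.4% at 500 bp and 43.7% at the midpoint, and in RIL-11272 34.3% and 33.6%. For windows called by level it was 60.1% at 500 bp in RIL-11268, at the doubled coverage minimum 50% in RIL-11268 and 52.2% in RIL-11272, and in CHG 34.6% in RIL-11268 and 23.0% in RIL-11272, below an even share where CG lay above it; the cause was not tested.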

Other observations

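The tests of depth in RIL-11268, of mixed DNA, of plants of another line, of both haplotypes, of a wrong line label, of mapping and of depth between the parents were chosen after the patterns were seen. Among genes under 1 in all 3 libraries of a parent and at least 5 in all 3 of the other, 25 were off in LD and on in LDX, and 42 were off in LDX and on in LD. Of the 25, RIL-11268 had 10 on and 10 off, and RIL-11272 had 9 on and 14 off, with on or off meaning at least 1 or under 1 in all 3 libraries. Of the 42, RIL-11268 had 32 on and 6 off, and RIL-11272 had 27 on and 11 off. The parental genes of chromosome 18 were LDX at 31 of 33 decided genes in RIL-11268, and at 13 of 32 in RIL-11272.

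RIL-11268 listed cytosines of both parental types over long stretches, most on chromosome 15, where both types had a dosage above 0.2 in 34 of 39 bins. Chromosomes 1, 3, 6, 7, 12 and 16 also held many such bins. They were not particular to this line: RIL-11272 had 7 of 11 on chromosome 13, 6 of 11 on 7 and 6 of 12 on 16. On chromosomes 15 and 3 it had 2 of 39 and 4 of 27. Low read depth is argued against, since missing reads cannot add cytosines of a type. On chromosomes 3 and 15 the smaller of both dosages had medians of 0.331 and 0.422 over bins and first quartiles of at least 0.157. The largest value of any bin on chromosomes 4 and 19 was 0.1499, but only these chromosomes had no bin with both types above 0.2. Chromosome 20, at 12.1% LDX by windows, had 8 of 30 such bins. That gap was thus set in part by the choice of chromosomes and adds little. DNA of LD, LDX or RIL-11272 mixed into the library is argued against by the type RIL-11268 lacks on chromosomes 4, 18 and 19, whose median dosage over bins was at most 0.0453; over whole chromosomes it was 0.170 on 18 and 0.147 on 4, with both types above 0.2 in 8 of 45 bins of 18, still below the medians of chromosomes 3 and 15. The RNA libraries of the line were intermediate on the same chromosomes, with r 0.698 over chromosomes and 20 of 32 parental genes on chromosomes 3 and 15 intermediate against 39 of 208 elsewhere (2-sided Fisher's exact p 8.89e-07, genes being linked and those chromosomes picked from the windows). Both parental haplotypes in plants of the line and plants of another inbred line among those sampled would each give this r and cannot be told apart, since the other inbred lines were not analysed here and the labels do not give the number of plants.

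LD replicate 2, LDX replicate 3 and RIL-11272 replicate 1 deviated together from their lines, with pairwise correlations of 0.698 to 0.874. A wrong line label is argued against: of the genes that separate the lines without these libraries, at least 91.5% were nearer the labelled line in each. Lower depth of these libraries as the whole cause is argued against. Of 1,644 genes with a mean of at least 100, 43.1% differed by 2-fold or more between these 3 and the other 9, 616 of them higher in the 3 and 93 lower. Lower depth as a part stays open. The commonest step between low values was 1.79, 1.45 and 1.66 times that of LD replicate 1, against 0.914 to 1.18 in the others. It held only 6.17%, 4.49% and 2.76% of low values. Genes at 0 numbered 23,958, 23,404 and 23,899, against at most 23,193 in the others. A few genes taking most of the reads would shift all others by 1 amount, whereas the log2 differences had a standard deviation of 0.925 about a median of -0.06, although the 10 leading genes held 4.49%, 6.47% and 10.2% of these libraries and their rescaled sums were the highest (1311490, 1369960 and 1605110, against at most 1048300). Time of day, position in the growth chamber and library preparation, none given per library in the labels, stay open, as does a biological difference between plants.

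Windows listed in 1 parent alone gathered in stretches of 1 direction. Sequencing 1 parent less deeply is argued against, as chromosome 19 had 95.3% of its windows in LDX alone and chromosome 4 87.9% in LD alone. Reads of 1 parent mapping less there is open and had the values it needs, over the 405 bins with at least 20 windows. There the log2 ratio of LD-alone to LDX-alone windows (1 added to each count) rose with that of LD to LDX reads at cytosines listed in both. Spearman rho was 0.690 (permutation p 1e-05, the smallest that 100000 permutations can give) and Pearson r 0.702. Sequence that is absent or diverged in 1 parent could thus account for some of the windows, with CHG and CHH cytosines seldom listed there either. A loss of methylation on sequence both parents carry stays open as well, and the genomic reads that could separate these were not analysed here.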
